A study of Mus musculus with 8 samples.

How the data were processed

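Whole-tissue RNA sequencing was analysed from 8 libraries of mouse vomeronasal epithelium, 2 in each of 4 groups given by sex and preparation. The labels give 8-week-old C57BL/6J mice, and they mark 4 libraries as non-flushed pools of 2 mice and 4 as flushed tissue of 1 mouse. Group and replicate were taken from these labels, and the replicate number of a single mouse was taken from its label, while pools were numbered in listed order. Libraries were made from polyA-selected RNA with a stranded kit and read as single ends of 100 nucleotides, per the labels' protocols. PCR duplicates cannot be told from separate molecules in such data.

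Reads were aligned with STAR 2.7.1a to GRCm38 (mm10) and counted with featureCounts 1.6.5, per the submitters' processing notes. The deposited values are expected counts, in that a read with several alignments added a fraction to each gene, per the file headers. Counting was reverse stranded, over exons grouped by gene, with no minimum mapping quality and without reads that overlapped more than 1 gene, per the file headers. The annotation was Ensembl GRCm38 with changes by the authors, per the file headers, and 50 of the 48831 genes carried identifiers of the authors' own. No normalization had been applied to these counts. Between 10.16 and 11.79% of genes in a library had a count that was not whole. Reads from near-identical receptor genes are divided evenly by this counting, so the level of any such gene is uncertain and differences between similar genes are diluted.

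Symbols came from GENCODE M21 by Ensembl identifier (48422 genes), and 150 retired identifiers were named by position. Of the former, 22 with a clone name were given a receptor symbol by position from a RefSeq annotation of the same build, and 209 Ensembl genes had no name. Genes without a name held 0.024% of counts. Intact receptor genes were those annotated as protein-coding, which includes a few whose symbol marks a pseudogene, and all others counted as pseudogenes. Among the pseudogenes, 48 of Vmn1r were named by the authors, and 38 of these had a count of 0 in every library.

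Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test after TMM normalization and filterByExpr on the 4 groups. The model held sex and preparation as additive terms, and an interaction term was tested in a further fit. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and every adjusted p of a gene in the text comes from this test unless DESeq2 or limma-voom is named. A total of 20601 genes passed the filter. The SE of a log2 difference is its size divided by the square root of its F statistic. A sex or preparation fit compares 4 libraries with 4, and groups of the interaction hold 2 libraries each. CPM values are unrounded counts divided by the TMM-scaled library size of the tested genes, and RPKM values also by the exon length per the file headers. The 39 gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and beside it an estimated correlation and fry, adjusted over all 39 lists. The estimated correlation of small lists from 8 libraries is itself imprecise. Counts of list members that rose or fell come from the edgeR test over all genes, and counts adjusted over the list alone repeat the adjustment within the list.

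Levels of receptor classes were compared by two-sided permutation tests over genes with 1e+05 resamples, which treat genes as independent although they are not. A gene was isolated when no other intact gene of its family lay within 500 kb. Spread between libraries was the residual SD of log2(CPM + 0.5) around the 4 group means for genes with a mean count of 20 or more. The list median was set against 10000 random gene lists matched on mean level. Its two-sided p came from the smaller of the shares of these lists at or above it and at or below it. The results call this value too a permutation p over genes, although no labels were permuted for it. Family shares were compared with exact permutation tests within the levels of the other factor.

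The genes named were chosen by a rule fixed before the data were examined. It takes the Y-linked and X-inactivation genes, and the 8 genes with the largest change in each direction among those past the threshold, with a mean log2 CPM of 1 or more, the same sign within both levels of the other factor, and a symbol other than a clone name. It adds the 3 genes with the smallest p of each list that passed, the 5 receptor genes with the smallest p in each comparison, the 3 with the highest mean RPKM in each family, and the isolated receptor genes if 10 or fewer. From the genes that this rule takes, a smaller set was picked for the text after their values were seen. The 10 interaction genes lie outside the rule, were named after their values were seen and are all that passed.

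Designs, lists and most alternatives were also set before the data were examined. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE size factors, no filter or a stricter filter on low counts, unrounded counts, a threshold of 0.01, models without the other factor, subsets of libraries or genes, other pseudocounts, count minimums and distances, library sizes over receptor genes, and leaving out each library. Chosen after seeing the data were a correction for GC content and length by smooth trends per library (mgcv 1.9.3), a library size over vomeronasal neuron markers, leaving out coding genes named as pseudogenes, levels within each preparation, splits of the libraries without X- and Y-linked genes or balanced for the other factor, and a check of the unfiltered fit. GC content came from the longest transcript and was known for 99.4% of tested genes and 91.1% of tested receptor genes. In the correction, genes without a known GC content were given the median of the tested genes.

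The edgeR step was tested on simulated data with 200 changed genes. For the sex comparison, run on 20288 genes, it recovered 56% of genes changed 1.5-fold, 78% at 2-fold, 96% at 3-fold and 96% at 4-fold, with 6 false among 169 calls. For the preparation comparison, run on 20286 genes, the shares were 50, 78, 98 and 96%, with 4 false among 165 calls. Each simulated gene took the spread typical of its mean level, and genes were drawn independently. The real libraries also hold spread particular to single genes, so these shares may be too high and the false calls too few for them. The permutation test called 3 of 100 simulated comparisons without a difference and 90 of 100 with a shift of 1 SD between a small and a large group of values. Single-cell data of the series were not analysed here.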

Results

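Whole-tissue RNA was sequenced from the vomeronasal epithelium, the sensory lining of the organ with which mice detect pheromones, of C57BL/6J mice aged 8 weeks. The 8 libraries formed 4 groups of 2, given by sex and by preparation. Each of the 4 non-flushed pools held tissue from 2 mice, and each of the 4 flushed libraries came from 1 mouse whose tissue the labels describe as flushed, a step that clears blood from the vessels. The protocol shared by all 8 labels says that mice were flushed with heparin, so it differs from the descriptions of the pools, and the descriptions were used here. Replicates were separate mice or separate pools, per the labels. Total counts per library ranged from 18763557 to 22096792 in the pools and from 22101913 to 24965088 in the flushed single mice. The series addresses the expression of vomeronasal receptor genes, and its title refers to their dispersion in the genome and to transcriptional instability. These genes comprise the Vmn1r and Vmn2r pheromone receptor families and a few formyl peptide receptors (Fpr-rs). Its design text also names single-cell sequencing, which was not analysed here. Coordinates are those of GRCm38, and values are mean ± SD over libraries.

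The first comparison asked which transcripts differed between males and females. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, used as a check of the labels, had between 582 and 2106 counts in every male library and at most 6 counts in any female library. Xist, the non-coding RNA of X inactivation (X, 103460375 to 103483217, minus strand), had between 9362 and 25631 counts in each female library and at most 24 in any male library. All 8 libraries therefore matched their labelled sex. Kdm6a, Eif2s3x and Kdm5c, X-linked genes that escape inactivation, were higher in females (n = 4 libraries per sex). Kdm6a was higher by 1.72-fold (log2 male minus female = -0.78, SE 0.08, edgeR adjusted p = 0.0028). Eif2s3x was higher by 1.34-fold (-0.42, SE 0.05) and Kdm5c by 1.33-fold (-0.41, SE 0.05), both with an edgeR adjusted p of 0.016.

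Beyond the sex chromosomes, genes of secreted odorant-binding proteins were among those higher in males. Lcn4, a lipocalin of the nasal glands (chromosome 2, 26667674 to 26671282), rose from 6460 ± 642 CPM in females to 9360 ± 584 CPM in males (n = 4 each, 1.45-fold, log2 difference 0.53, SE 0.07, edgeR adjusted p = 0.028). Obp2a, an odorant-binding protein gene (chromosome 2, 25700043 to 25703326), rose from 38200 ± 4600 to 56900 ± 8060 CPM (n = 4 each, 1.48-fold, log2 difference 0.57, SE 0.08, edgeR adjusted p = 0.03). Its neighbour Obp2b had a difference of 0.50 that did not pass the test (edgeR adjusted p = 0.065). Gad1, an enzyme of GABA synthesis, was higher in males by 1.86-fold (18.1 ± 2.33 against 9.81 ± 2.06 CPM, edgeR adjusted p = 0.028). Sptb, the spectrin of red blood cells, was higher by 1.84-fold (edgeR adjusted p = 0.013) and Dact2, a modulator of Wnt signalling, by 1.63-fold (edgeR adjusted p = 0.011). In all, 24 of 20601 tested genes differed by sex, 17 higher and 7 lower in males, and 12 of them were autosomal. DESeq2 called 123 genes, among them all 24. Without X- and Y-linked genes, whose small p-values ease the adjustment of the others, 3 genes passed, and Gad1 (edgeR adjusted p = 0.073), Lcn4 (0.084) and Obp2a (0.095) did not. Lcn4 and Obp2a also missed the threshold with limma-voom (adjusted p = 0.06 and 0.079). Without male non-flushed pool 1 the count was 8, without female non-flushed pool 1 it was 12 and without flushed female 3 it was 15. With 1 library left out, the edgeR adjusted p exceeded 0.05 for Kdm5c (0.092 at most, in all 8 fits), Eif2s3x (0.081 at most, 4 fits), Gad1 (0.14 at most, 6 fits), Lcn4 (0.12 at most, 6 fits), Obp2a (0.12 at most, 5 fits), Sptb (0.081 without male pool 1, 0.054 without flushed female 3) and Dact2 (0.078 without male pool 1).

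Of 313 vomeronasal receptor genes tested, 3 differed by sex, and all 3 belonged to the Vmn2r family. Vmn2r58 (chromosome 7, 41831120 to 41872670, minus strand) had 14.8 ± 4.18 CPM in females and 5.78 ± 2.32 CPM in males (n = 4 each), a 2.61-fold lower level in males (log2 difference -1.38, SE 0.10, edgeR adjusted p = 0.00015). Vmn2r121, on the X chromosome (124126516 to 124135910, minus strand), fell from 56.1 ± 21.4 to 32.3 ± 11.3 CPM, or 1.72-fold (log2 difference -0.78, SE 0.09, edgeR adjusted p = 0.011). Vmn2r92 (chromosome 17, 18151930 to 18194977) was 1.56-fold higher in males, at 21.6 ± 9.22 against 13.5 ± 4.57 CPM (log2 difference 0.64, SE 0.10), with an edgeR adjusted p that rounds to 0.05 and lies under the threshold. The SDs span both preparations, and within each preparation the 2 libraries of each sex lay on separate sides for all 3 genes. Adjusted over the list alone, 6 receptor genes differed by sex, 2 higher and 4 lower in males. Vmn2r29 (log2 difference -0.69, edgeR adjusted p = 0.18) and Vmn2r116 (-0.42, edgeR adjusted p = 0.18) did not pass over all genes and passed with DESeq2 (adjusted p = 0.039 and 0.034), which called 5 receptor genes. Vmn2r58 passed without any 1 of the 8 libraries (edgeR adjusted p of 0.0025 at most), Vmn2r121 lost its call without male non-flushed pool 1 (0.075), which left 1 receptor gene called, and Vmn2r92 lost it in each of the 8 such fits (0.077 to 0.19) and without X- and Y-linked genes (0.095). Reads of Vmn2r121 and Vmn2r92 were shared with other genes in 8 of 8 libraries and those of Vmn2r58 in 5, so part of their counts was divided between similar genes.

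**Figure D1:**
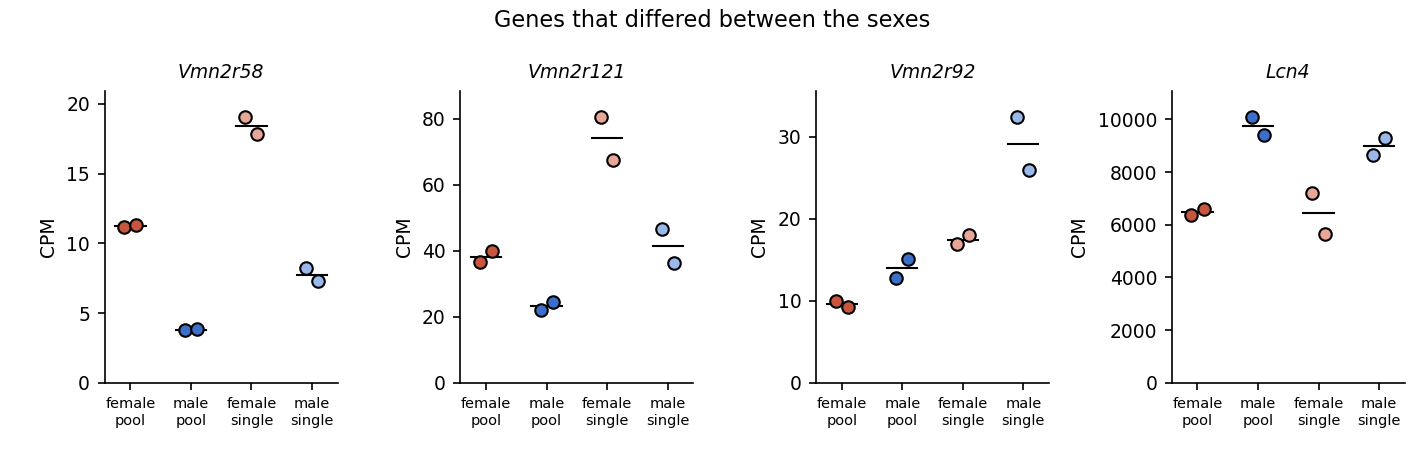
Expression in CPM (linear axis from 0) of 3 receptor genes and Lcn4 in each of the 8 libraries, by sex and preparation, with a horizontal line at the mean of the 2 libraries of a group. Vmn2r58 and Vmn2r121 were lower in males and Vmn2r92 and Lcn4 higher in males within both preparations.

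The receptor families as wholes lay close to 0 between the sexes. The median log2 difference was -0.04 for the 149 intact Vmn1r genes tested, of which 0 passed, and -0.049 for the 120 intact Vmn2r genes, of which 1 rose and 2 fell. Markers of vomeronasal sensory neurons such as the common list (12 genes, median 0.005), the apical list (7 genes, median 0.03) and the basal list (9 genes, median -0.004, mean 0.039) held 0 genes past the test, over all genes or adjusted over the list alone. Among lists that shifted as a whole with a preset correlation, the erythroid genes had a median log2 difference of 1.304 toward males (14 genes, camera adjusted p = 4.94e-09; adjusted p = 0.276 with an estimated correlation). The platelet genes had a median of 1.07 (9 genes, camera adjusted p = 6.64e-09; adjusted p = 0.276 with an estimated correlation). The erythroid median was 2.37 in flushed single mice and 0.218 in pools, and the platelet median 1.744 and 0.543 (2 libraries per sex, a difference not tested for the lists). No gene of the erythroid or platelet list passed over all genes tested, and 11 and 7 of them did adjusted over the list alone. Sptb, which passed, is not on the erythroid list. Slc4a1, an anion exchanger of red cells, had a log2 difference of 1.55 (edgeR adjusted p = 0.25) and Gp5, a platelet glycoprotein, one of 1.07 (edgeR adjusted p = 0.31). In the secretory and glandular list, 2 of 20 genes, Lcn4 and Obp2a, rose in males, and 10 differed adjusted over the list alone (camera adjusted p = 2.88e-05, and 0.587 with an estimated correlation). The circadian clock list had a median of 0.132 (16 genes, camera adjusted p = 0.000171; adjusted p = 0.206 with an estimated correlation) and the ciliated respiratory list one of -0.363 (13 genes, camera adjusted p = 1.19e-05; adjusted p = 0.768 with an estimated correlation). Macrophage (median -0.133), endothelial (-0.102), interferon (-0.15) and intact-named Vmn2r genes (-0.051) also passed with the preset correlation (camera adjusted p = 0.000778, 0.0404, 0.0167 and 0.0273). With an estimated correlation their adjusted p was 0.587, 0.673, 0.915 and 0.915. Adjusted over the list alone, 4 circadian, 1 ciliated, 0 macrophage, 1 endothelial, 0 interferon and 8 intact-named Vmn2r genes differed. Of the 11 lists that passed out of 39, the Y-linked (4 of 4 rose) and X-inactivation lists (5 of 9 fell) kept their call with an estimated correlation (adjusted p = 0.00786 for both).

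The second comparison set the 4 flushed single mice against the 4 non-flushed pools. Blood transcripts were lower in the flushed libraries. The haemoglobin gene Hba-a1 (chromosome 11, 32283511 to 32284465) fell from 381 ± 34.2 to 76.8 ± 64.1 CPM (n = 4 each, 6.98-fold, log2 difference -2.80, SE 0.42, edgeR adjusted p = 0.0005). Hbb-bs (chromosome 7, 103826534 to 103828096) fell from 643 ± 74.3 to 119 ± 92.4 CPM (7.18-fold, log2 difference -2.84, SE 0.37, edgeR adjusted p = 0.00025). Alas2, the first enzyme of haem synthesis in red cell precursors, fell by 4.99-fold (edgeR adjusted p = 0.00022). These folds come from the additive fit and are not ratios of the means. The falls were larger in females (log2 difference -4.03 for Hba-a1, -3.92 for Hbb-bs and -3.37 for Alas2) than in males (-1.64, -1.79 and -1.52). Of 14 erythroid genes, 12 fell and 0 rose (camera adjusted p = 0.000111; adjusted p = 0.347 with an estimated correlation), and 12 passed adjusted over the list alone. Of 13 neutrophil genes, 10 fell, with S100a9 4.25-fold lower (camera adjusted p = 0.0018; adjusted p = 0.548 with an estimated correlation). Of 9 platelet genes, 6 fell, with Itga2b 2.36-fold and Pf4 1.57-fold lower (camera adjusted p = 0.00774; adjusted p = 0.533 with an estimated correlation). Adjusted over the list alone, 12 neutrophil and 7 platelet genes differed. The Pf4 call was lost without any 1 of 5 libraries (edgeR adjusted p of 0.063 at most), and with GC content and length corrected (edgeR adjusted p = 0.08).

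Several immunoglobulin genes were higher in the flushed libraries. Ighg2c, an immunoglobulin heavy chain constant gene (chromosome 12, 113285325 to 113288932, minus strand), had 0.149 ± 0.118 CPM in pools and 83.2 ± 46.5 CPM in flushed single mice (n = 4 each, log2 difference 9.15, SE 0.67, edgeR adjusted p = 2e-05). Iglc1, a light chain constant gene, rose from 0.868 ± 0.714 to 30.2 ± 40.8 CPM (log2 difference 4.67, SE 0.91, edgeR adjusted p = 0.0022). Its level was 91.3 CPM in flushed male 1 and 6.11 to 12.2 CPM in the other flushed libraries, and the log2 difference was 3.44 without that library and 5.96 without female pool 1. The variable segment Ighv1-54 had a count of 0 in all 4 pools and 11 ± 17.2 CPM in flushed single mice, where its level ran from 0.379 to 36.7 CPM (edgeR adjusted p = 0.0037). All 8 genes with the largest rise under the naming rule were immunoglobulin genes, a class not tested as a list. The heavy chain gene Ighm did not move one way, with 18.8 and 13.7 CPM in female pools and flushed females and 17.5 and 48.0 CPM in male pools and flushed males (n = 2 each). In the lymphocyte list 6 of 15 genes rose and 3 fell (median 0.536, camera adjusted p = 0.257). Krt10 and Krt1, keratins of cornified epithelium, were lower in flushed single mice by 21.6-fold (edgeR adjusted p = 0.018) and 16.9-fold (edgeR adjusted p = 0.041). This rested on male non-flushed pool 1, where Krt10 had 60.8 CPM against at most 1.78 CPM in any other library. Without that pool the log2 differences were -1.23 (edgeR adjusted p = 0.06) and -0.62 (edgeR adjusted p = 0.44), and the calls were also lost without either flushed male (0.099 and 0.17 at most) and, for Krt1, without female pool 1 (0.055) or flushed female 2 (0.068).

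Connective tissue and activity-dependent genes fell in the flushed libraries. Col1a1, a fibrillar collagen gene, fell 2.46-fold (17500 ± 3090 to 7070 ± 1190 CPM, log2 difference -1.30, SE 0.09, edgeR adjusted p = 1.7e-05) and Col3a1 fell 2.09-fold (log2 difference -1.06, SE 0.07, edgeR adjusted p = 1.4e-05). In the list, 8 of 13 fibroblast and matrix genes fell while 2 rose (camera adjusted p = 0.00774; adjusted p = 0.347 with an estimated correlation). Dmp1, a matrix protein of osteocytes, fell 3.36-fold (170 ± 10.9 to 50.5 ± 7.73 CPM, edgeR adjusted p = 1.4e-05). Of the bone list, 8 of 12 genes fell while 1 rose (camera adjusted p = 0.00472; adjusted p = 0.548 with an estimated correlation). Of 17 immediate early genes, which cells transcribe soon after stimulation, 13 fell and 0 rose (camera adjusted p = 0.000344; adjusted p = 0.347 with an estimated correlation). Fos fell 2.32-fold (edgeR adjusted p = 0.00075) and Junb 2.22-fold (edgeR adjusted p = 4.7e-05). Cartilage genes fell in 7 of 11 cases, endothelial genes in 8 of 14, smooth muscle and pericyte genes in 6 of 13 and basal or proliferating cell genes in 7 of 13, and 1 gene rose in each of these lists but the endothelial one (camera adjusted p = 0.029, 0.0034, 0.00774 and 0.0356). With an estimated correlation their adjusted p was 0.443, 0.347, 0.548 and 0.617. In the ribosomal protein list 49 of 82 genes fell and 5 rose (camera adjusted p = 1.53e-07; adjusted p = 0.548 with an estimated correlation). Of 16 mitochondrially encoded genes, 13 rose and 1 fell (camera adjusted p = 0.000344; adjusted p = 0.347 with an estimated correlation). The mitochondrial share of all counts was 0.27 to 0.32% in pools and 0.57 to 0.69% in flushed single mice. Adjusted over the list alone, 10 matrix, 9 bone, 13 immediate early, 9 cartilage, 9 endothelial, 8 smooth muscle, 8 basal, 56 ribosomal and 14 mitochondrially encoded genes differed. Markers common to vomeronasal sensory neurons had a median of -0.077, with 0 of 12 genes higher and 1 lower.

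Of 313 vomeronasal receptor genes tested, 232 were higher and 0 lower in flushed single mice with the library size taken over all genes. With the library size taken over receptor genes alone 44 were higher and 50 lower. That size removes any shift common to the receptor genes, so it cannot show whether they rose together. The values that follow rest on the library size over all genes. The median log2 difference was 0.84, with quartiles of 0.57 and 1.08, and adjusted over the list alone 250 genes rose and 1 fell. Of intact genes, 102 of 149 Vmn1r, 108 of 120 Vmn2r and 4 of 5 Fpr-rs genes rose, and among pseudogenes 16 of 30 Vmn2r and 2 of 9 Vmn1r. Vmn1r71 (chromosome 7, 10747502 to 10749538) rose from 6.90 ± 1.01 to 20.6 ± 1.46 CPM (n = 4 each, 3-fold, log2 difference 1.58, SE 0.09, edgeR adjusted p = 1.4e-05). Vmn2r105 (chromosome 17, 20202326 to 20234872) rose from 13.1 ± 0.402 to 29.7 ± 1.07 CPM (2.27-fold, edgeR adjusted p = 1.4e-05) and Vmn2r53 from 28.1 ± 1.49 to 59.3 ± 6.25 CPM (2.11-fold, edgeR adjusted p = 1.4e-05). The pseudogene Vmn2r-ps42 rose 3.15-fold (edgeR adjusted p = 1.4e-05) and the formyl peptide receptor Fpr-rs3 1.83-fold (edgeR adjusted p = 4.7e-05). The lists of intact-named Vmn2r (119 genes, camera adjusted p = 3.63e-32), intact-named Vmn1r (148 genes, 1.8e-19) and pseudogene-named Vmn2r genes (31 genes, 5.53e-08) passed. So did those of family C Vmn2r (6 of 6 rose, camera adjusted p = 6.94e-05) and formyl peptide receptor genes (4 of 5 rose, 0.00349). With an estimated correlation their adjusted p was 0.324, 0.324, 0.324, 0.347 and 0.324. Adjusted over the list alone, 111, 109, 19, 6 and 5 genes of these lists differed.

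The difference by preparation followed GC content across genes. Over the tested genes with a known transcript, GC content and the log2 difference correlated at a Spearman's rho of -0.68, which is across genes, and genes are not independent replicates. Among genes other than receptors, the median log2 difference was 0.575 at a GC content of 37.5 to 40% and -0.229 at 52.5 to 55%. Receptor genes had a median GC content of 39% against 49% for the others. With GC content and length corrected, the receptor median was 0.326 (quartiles 0.033 and 0.536), with 108 receptor genes higher and 4 lower in flushed single mice. These values include receptor genes without a known GC content, which were given the median of the tested genes. They could not be corrected for their own GC content, as for Vmn1r218 (0.554 before and 0.525 after). By step of known GC content, corrected receptor medians ran from 0.116 (8 genes at 32.5 to 35%) to 0.47 (18 genes at 42.5 to 45%). The largest step, 134 genes at 37.5 to 40%, had 0.214. The same correction left 4412 genes, of which 3177 were shared with the 9377 called without it. In that fit 11 of 14 erythroid, 6 of 13 neutrophil, 2 of 9 platelet, 8 of 12 bone, 7 of 13 matrix, 8 of 17 immediate early and 26 of 82 ribosomal protein genes were lower. So were 5 of 14 endothelial, 4 of 11 cartilage, 8 of 13 basal or proliferating cell and 2 of 13 smooth muscle and pericyte genes, and the last list had a median of -0.092 in place of -0.286. Of mitochondrially encoded genes 3 of 16 were higher, and the median of the Y-linked list turned from 0.399 to -0.238.

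**Figure D2:**
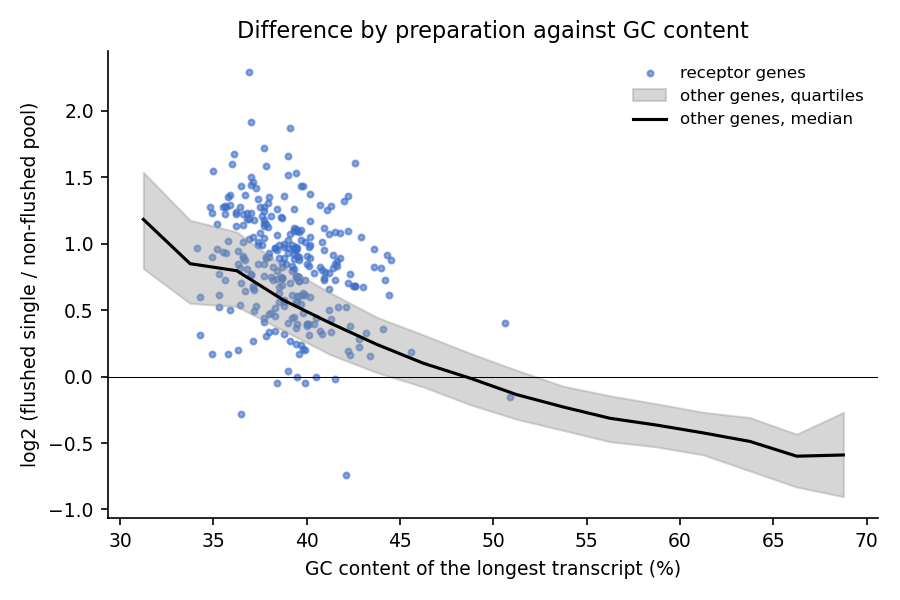
Log2 difference between flushed single mice and non-flushed pools (vertical axis) against the GC content of the longest transcript in percent (horizontal axis), with the library size taken over all genes. Points are receptor genes, and the line and band are the median and quartiles of other genes in steps of GC content. The median runs from 1.182 at 30 to 32.5% down to -0.59 at 67.5 to 70%. With the library size over receptor genes alone, which removes their common shift, 50 of the receptor genes called lie below 0 and 44 above.

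In all, 9377 of 20601 genes (45.5%) differed by preparation, 4656 higher and 4721 lower in flushed single mice, and 19 of 39 lists passed with the preset correlation against 0 with an estimated one. Run date, lane, pooling and flushing all changed together: the file headers hold 2 run dates and 0 of them cover both preparations, so these cannot be told apart. Within males alone 4770 genes passed and within females alone 4703.

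The third comparison asked whether the sex difference depended on the preparation, by an interaction term. Haemoglobin genes had a larger sex difference among flushed single mice than among pools. Hba-a1 stood at 353 and 410 CPM on average in female and male pools, and at 21.6 and 132 CPM in flushed females and males (n = 2 each), an interaction of 2.39 on the log2 scale (SE 0.14, edgeR adjusted p = 0.00034). Hba-a2, Hbb-bt and Hbb-bs had interactions of 2.37, 2.19 and 2.12 (edgeR adjusted p = 0.000359, 0.000359 and 0.000642) and Alas2 one of 1.84 (edgeR adjusted p = 0.00625). Ighm, the heavy chain of IgM, was higher in flushed males (48.0 CPM) than in the other 3 groups (13.7 to 18.8 CPM), with an interaction of 1.91 (SE 0.21, edgeR adjusted p = 0.0142). The 4 genes with a negative interaction had their lowest mean level in flushed males. The interactions were -3.77 for Sbp, a spermine-binding protein gene (edgeR adjusted p = 0.0232), and -3.93 for its neighbour Sbpl (0.0142). Those of Tff2, a trefoil factor of mucus, and Chil4, a chitinase-like secreted protein, were -3.17 (0.0491) and -5.28 (0.0441). Of 20601 genes tested, 670 had an unadjusted edgeR p under 0.05, a share below the 0.05 expected without any interaction. DESeq2 called 27 genes. In all, 10 genes passed the edgeR test, 6 positive and 4 negative, and 0 of 313 receptor genes did. The count was 4 without flushed female 3, 5 without flushed male 3, 6 without flushed male 1 or male pool 1, and 18 without female pool 2.

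**Figure D3:**
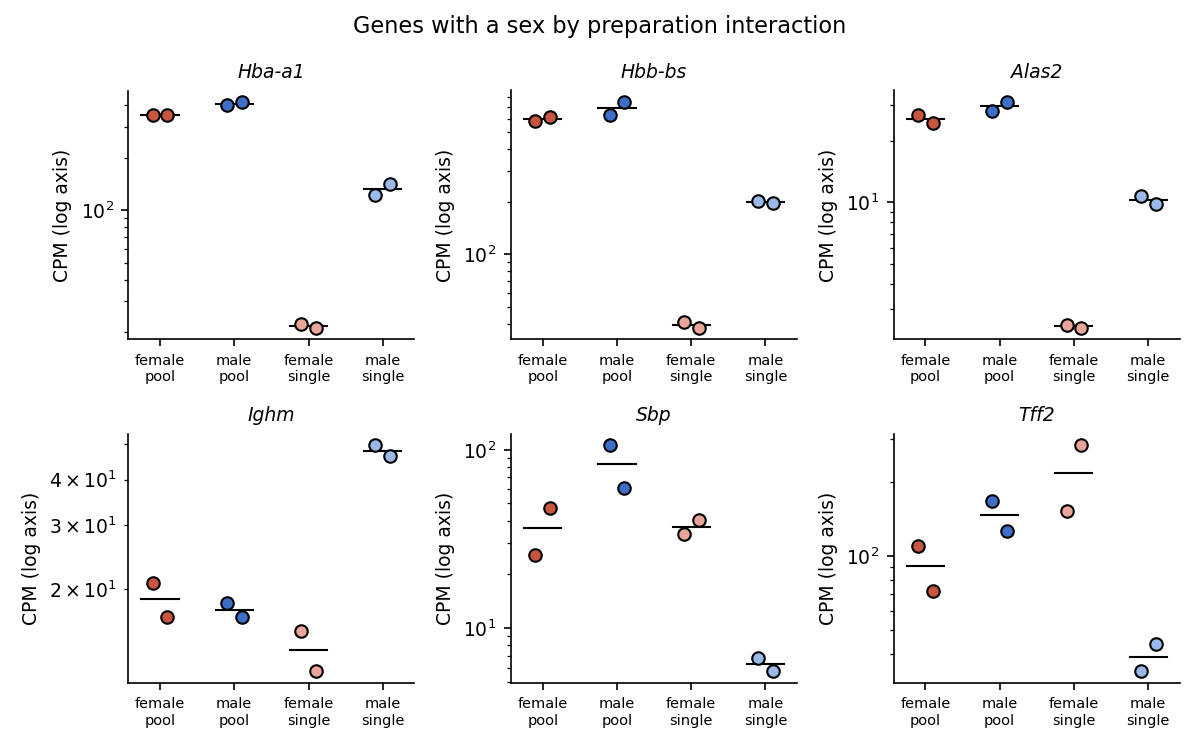
Expression in CPM (log axis) of 6 genes with a sex by preparation interaction in each of the 8 libraries, with a horizontal line at the mean of the 2 libraries of a group. The haemoglobin genes and Alas2 were lowest in flushed females, Ighm was highest in flushed males, and Sbp and Tff2 were lowest in flushed males.

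Receptor transcripts made up a small part of the tissue's RNA. Vmn1r genes took 0.0697 ± 0.023% of all counts, Vmn2r genes 0.241 ± 0.095% and Fpr-rs genes 0.00418 ± 0.0015% (SD, n = 8). The share in flushed single mice was 1.87 times that in pools for Vmn1r, 2.12 times for Vmn2r and 2.01 times for Fpr-rs genes, with every flushed library above every pool. For each family the two-sided exact permutation p within sexes was 0.056, which is the smallest that the 36 arrangements allow. Male over female ratios were 0.937, 0.894 and 0.95 (exact permutation p within preparations = 0.22, 0.11 and 0.67). Averaged over all 8 libraries, the highest levels were those of Vmn2r6 (33.9 ± 11 RPKM, n = 8, chromosome 3, 64537561 to 64565298), Vmn2r89 (31.7 ± 11 RPKM) and Vmn2r2 (26.1 ± 7.78 RPKM) in the Vmn2r family. Vmn1r35 (14.3 ± 3.81 RPKM), Vmn1r85 (12.5 ± 5.01 RPKM) and Vmn1r89 (7.17 ± 0.973 RPKM) were highest in the Vmn1r family, and Fpr-rs3 (3.45 ± 1.12 RPKM), Fpr3 (3.12 ± 1.12 RPKM) and Fpr-rs4 (0.994 ± 0.402 RPKM) among the formyl peptide receptors. The order depended in part on the preparation, as Vmn1r71 stood above Vmn1r89 in flushed single mice and Fpr-rs7 (0.641 RPKM) beside Fpr-rs4 (0.638 RPKM) in pools (n = 4 each).

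Intact receptor genes, those annotated as protein-coding, were expressed above pseudogenes of their family. On the log2(RPKM + 0.1) scale, the 227 intact Vmn1r genes averaged -0.91 ± 1.78 and the 153 pseudogenes -2.98 ± 0.84 (SD over genes), a difference of 2.07. The 123 intact Vmn2r genes averaged 0.50 ± 1.80 and the 101 pseudogenes -2.18 ± 1.53, a difference of 2.68. Both had a two-sided permutation p over genes of 1e-05, the smallest that the resamples can give, and the direction held in 8 of 8 libraries. The size of the difference depended on the pseudocount, as many pseudogenes lie at the floor. With a pseudocount of 0.01 it was 4.09 for Vmn1r and 4.31 for Vmn2r, and with 1 it was 0.68 and 1.13. At a count of 0 in every library were 97 Vmn1r and 32 Vmn2r pseudogenes, against 0 intact genes of either family. Among genes with a mean count of 20 or more, the difference was -0.55 for Vmn1r (125 intact genes, 4 pseudogenes, permutation p = 0.44) and 0.38 for Vmn2r (113 and 19 genes, permutation p = 0.33). This filter selects on the level that is compared and removes most pseudogenes for being low, so it cannot decide whether the difference holds.

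**Figure D4:**
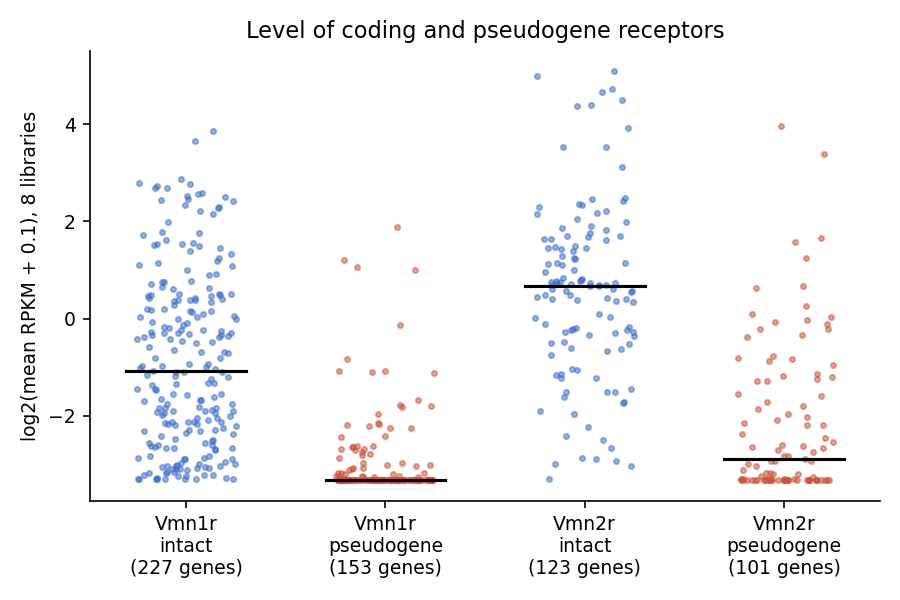
Mean level over the 8 libraries of each receptor gene as log2(RPKM + 0.1), for intact genes and pseudogenes of both families, with 1 point per gene and a horizontal line at the median. Intact genes extend over the whole range, while 97 of 153 Vmn1r and 32 of 101 Vmn2r pseudogenes lie at the floor because they had a count of 0 in every library.

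The title's question of dispersion was addressed by comparing isolated receptor genes with clustered ones. Among intact genes, 10 had no other intact gene of their family within 500 kb. Their mean levels ran from 0.00768 ± 0.013 RPKM for Vmn1r238 (chromosome 18, 3122492 to 3123412) to 25 ± 8.3 RPKM for Vmn2r-ps159 (chromosome 4, 156331103 to 156339499). Between these lay Vmn1r239-ps, Vmn2r118 and Vmn1r1 (0.299, 0.592 and 0.835 RPKM), Vmn1r90, Vmn2r18 and Vmn2r120 (1.42, 1.43 and 1.51 RPKM), and Vmn2r28 and Vmn2r121 (5.04 and 11.4 RPKM). Vmn2r-ps159 and Vmn1r239-ps carry pseudogene names although they are annotated as coding. Both families were pooled in this comparison, and intact Vmn2r genes lay above intact Vmn1r genes (log2 means of 0.50 and -0.91). Vmn2r genes were the larger part of the isolated genes but not of all intact ones (123 Vmn2r and 227 Vmn1r). The mix of families therefore adds to the difference, which was not tested within a family. The isolated genes averaged 0.66 ± 2.29 and the 338 clustered genes -0.46 ± 1.88 on the log2(RPKM + 0.1) scale, a difference of 1.12 that did not pass (permutation p over genes = 0.066). It passed with a distance of 250 kb (14 isolated genes, difference 1.35, permutation p = 0.0081) and with a pseudocount of 1 (difference 0.66, permutation p = 0.036). It did not pass without the coding genes named as pseudogenes (difference 0.9, permutation p = 0.18), with pseudogenes counted as neighbours (1.12, 0.12), with a pseudocount of 0.01 (1.32, 0.11) or without length (1.24, 0.14). Among genes with whole counts in every library only 2 isolated genes were left, too few to bear on it (against 40 clustered genes, difference 0.23, permutation p = 0.89).

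Variation between libraries of a group, the only form of instability that bulk libraries show, was compared with that of other genes, and over all 8 libraries the difference did not pass. The median residual SD of 266 receptor genes with a mean count of 20 or more was 0.171 on the log2 scale, and random lists matched on mean level gave a middle value of 0.165 (central 95% 0.153 to 0.178, two-sided permutation p over genes = 0.37). With a mean count of 100 or more, the 148 remaining genes had a median of 0.15 against 0.133 in matched lists (permutation p over genes = 0.013). Among flushed single mice the median was 0.156 against 0.132 (permutation p over genes = 4e-04), and among pools 0.147 against 0.165 (0.029), so the direction differed between preparations, and that difference was not itself tested. The change of direction lay in the Vmn2r family, with 0.155 against 0.114 in flushed single mice and 0.111 against 0.149 in pools (permutation p over genes = 2e-04 for both). Such p-values treat genes as independent, although genes of a family can move together. The Vmn2r share of counts was 0.331 and 0.285% in flushed males and 0.362 and 0.329% in flushed females. In pools of 2 mice it was 0.143 and 0.149% in males and 0.157 and 0.168% in females. The spread within a preparation rests on these 2 libraries per sex. Vmn1r genes lay above matched lists in both preparations, with 0.16 against 0.153 (0.57) and 0.218 against 0.192 (0.094). Without female pool 1 or female pool 2 the median was 0.174 (permutation p over genes = 0.001 and 0.0054). Without flushed female 2 or 3 it was 0.165 and 0.166 and lay below that of matched lists (0.69 for both). The 8 isolated genes measured had a mean SD of 0.187 and the clustered genes 0.18 (difference 0.007, permutation p over genes = 0.79), and the sign turned without flushed male 1 (-0.001) or flushed male 3 (-0.003).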

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

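The tests of residual blood and of a sex difference in both preparations were chosen only after the result was seen. Groups of 2 libraries are too small to look for single outlying samples.

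The sex difference of 10 genes differed between the 2 preparations by the edgeR interaction test, and 9 of them are autosomal. The interactions on the log2 scale were 2.39 for Hba-a1, 2.19 for Hbb-bt, 2.37 for Hba-a2, 2.12 for Hbb-bs, 1.84 for Alas2 and 1.91 for Ighm. They were -3.93 for Sbpl, -3.77 for Sbp, -5.28 for Chil4 and -3.17 for Tff2, each with 2 libraries per group.

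The first pattern weighed is that haemoglobin genes were lower in flushed females than in flushed males, with a median interaction of 2.284. A sex difference in erythroid transcripts of equal log2 size in both preparations would give no interaction, so it cannot account for that part. Whether such a difference adds to the one among flushed mice stays open. The haemoglobin medians of 0.216 in pools and 2.524 in flushed single mice restate the interaction by which these genes were found. In the same order, the 9 erythroid genes other than the haemoglobins and Alas2 had medians of 0.233 (quartiles 0.041 and 0.755) and 0.317 (0.062 and 2.455). These medians met the bound set for a sex difference in both preparations, for those 9 genes only and not for the haemoglobins. Sptb, outside the list, was higher in males in pools (24.7 and 19.9 against 13.7 and 13.6 CPM). In flushed single mice it was also higher in males (11.5 and 11.9 against 5.26 and 5.80 CPM). More blood left in the flushed males may account for the haemoglobin pattern, and the platelet and neutrophil lists had median interactions of 1.497 and 1.727 in the same direction. It also stays open, because those 9 genes had a median interaction of 0.539, with quartiles of 0.081 and 1.7, which met neither bound set for this test. A difference between the sexes in how the flush worked, or in the mice themselves, was not tested separately, and each flushed group holds 2 mice.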

How the results depend on the processing

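The GC and length correction, the check of the unfiltered fit and the library size over neuron markers were chosen only after the result was seen. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers in the labels. Each fit without 1 library assumes that the lone library of its group varies like the others. RLE size factors and unrounded counts left every count of genes within 1.5 times. For named genes, 649 values under alternatives kept direction and side of the threshold, 104 kept direction and lost the call, 10 gained it and 0 turned. The cause of the changes below was not tested unless one is given.

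Genes differing by sex (24) numbered 123 with DESeq2, 784 without a low-count filter, 7 without the preparation term, 3 without X- and Y-linked genes, 5 in pools alone (fewer samples), 8 at an adjusted p under 0.01, and 8 to 25 without 1 library. Without the filter 32514 genes were tested and the prior degrees of freedom were infinite, against 5.26 with it, so the spread of single genes was ignored, and 12 other splits of the libraries then called over 100 genes, up to 757. Receptor genes differing by sex (3) numbered 5 with DESeq2, 10 without a filter and 1 to 2 without 1 library. Genes differing by preparation (9377) numbered 4770 in males and 4703 in females (fewer samples), 6128 at an adjusted p under 0.01, 4412 after the GC and length correction and 7734 to 9047 without 1 library. Receptor genes differing by preparation (232) numbered 94 with the library size over receptor genes alone (44 higher, 50 lower, as that size removes their common shift), 112 after the correction, 233 over neuron markers and 215 to 227 without 1 library. Interaction genes (10) numbered 27 with DESeq2, 263 without a filter and 4 to 18 without 1 library. Lists by sex (11) numbered 2 with an estimated correlation and 2 with fry, and lists by preparation (19) numbered 0 and 22.

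A mean count of 20 or more selects on the level compared, so it cannot check the difference between intact genes and pseudogenes. With it, intact minus pseudogene levels turned for Vmn1r (-0.55, 4 pseudogenes left) and lost the call with the same direction for Vmn2r (0.38). Without 1 library the intact minus pseudogene levels were 2.04 to 2.1 for Vmn1r and 2.63 to 2.72 for Vmn2r. Their size depended on the pseudocount, at 4.09 and 4.31 with 0.01 and at 0.68 and 1.13 with 1. Isolated minus clustered levels (1.12), with both families pooled, passed at 250 kb (1.35) and with a pseudocount of 1 (0.66), and were 1.1 to 1.14 without 1 library. Receptor spread (0.171) passed at a count of 100 or more (0.15) and in flushed single mice (0.156), lay below matched lists in pools (0.147), and was 0.162 to 0.174 without 1 library. It lay below matched lists without flushed female 2 (0.165) or 3 (0.166). The isolated minus clustered spread (0.007) was -0.007 at 250 kb, -0.023 at a count of 100 or more and -0.023 in pools. Without 1 library it was -0.003 to 0.014, and -0.001 without flushed male 1. Depth limits genes near 20 counts, where counting noise enters the spread.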

Other observations

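The tests of neuron share, sequencing run, basal neuron share, GC content as the whole or a part of the cause, and splits without X- and Y-linked genes or balanced for the other factor were chosen only after the result was seen, as was the correction for GC content and length.

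Further lists by preparation passed the preset test. Olfactory receptor genes of the main olfactory system had a median log2 difference of 1.256 toward flushed single mice, with 3 of 8 genes higher (camera adjusted p = 0.0356; adjusted p = 0.347 with an estimated correlation), and one of 0.504 with 0 of 8 genes higher after the GC and length correction. X-inactivation and escape genes had a median of 0.462, with 7 of 9 higher and 1 lower (camera adjusted p = 0.0115; adjusted p = 0.347 with an estimated correlation), and of 0.051 after the GC and length correction. Other cell type lists did not pass. Skeletal muscle genes had a median of -0.742, with 2 of 14 lower (camera adjusted p = 0.108), and lymphocyte genes one of 0.536 (camera adjusted p = 0.257). Sustentacular cells had a median of 0.243, main olfactory neurons 0.243, macrophages -0.024, immature neurons -0.119, ciliated cells -0.095 and vomeronasal MHC class Ib genes -0.009. Glial genes fell in 7 of 13 cases (median -0.283, camera adjusted p = 0.0601). The share of counts in small nuclear and other non-coding RNA was 5.56 to 7.77% in pools and 2.87 to 4.05% in flushed single mice.

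The second pattern weighed is the higher level of receptor genes in flushed single mice. Its median was 0.84 with the library size over all genes. With the library size over receptor genes alone, which removes their common shift, 44 receptor genes were higher and 50 lower. Reads shared between receptor genes are argued against as the whole cause, since the 44 tested genes with whole counts in every library had a median of 0.904. Intact genes of that kind, before the filter on low counts, numbered 39 in Vmn1r and 3 in Vmn2r. For intact Vmn2r genes the test therefore cannot decide. GC content and length are argued against as the whole cause, because the highest of 10000 matched lists reached 0.646, but they may be part of it, since the middle of those lists was 0.545, and the excess of 0.301 over that middle did not reach the bound set in advance for excluding the bias. For a larger share of sensory neurons, the first bound asked that the upper quartile of the common markers lie below the receptor lower quartile. That held before the correction (0.04 against 0.57) but not after it (0.204 against 0.033). A second, looser bound took the 28 markers of the common, apical and basal neuron lists. Their corrected upper quartile was 0.187, below the receptor median of 0.326. By the looser bound alone, such a share is argued against as the whole cause, and the 0.326 includes receptor genes without a known GC content. Such a share stays open as a part of the cause (common markers had a median of -0.077 before and 0.043 after the correction), and so do flushing, pooling and the sequencing run, as 0 run dates hold both preparations.

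The third pattern weighed is the sex difference of Vmn2r58, Vmn2r121 and Vmn2r92. A different share of basal neurons is argued against, because the genes moved in opposite directions and intact Vmn2r genes had a median of -0.049. The real split alone gave as many receptor genes (1 of 34, 3 against 0 at most in the others), but sex-linked genes ease the adjustment in that split. Without X- and Y-linked genes 1 receptor gene passed, Vmn2r58 (1 of 34, against 0 at most in the others). Vmn2r92 lost its call there, while Vmn2r121 is X-linked and was itself left out. Reads shared between paralogs stay open and could shift the size of the differences, since 0 of the 3 genes had whole counts in every library. A biological difference between the sexes stays open and was not tested further.

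Splits of the 8 libraries into 4 and 4 that match the other factor could not be fitted and are left out. Of the 34 others, 18 hold 2 libraries of each level of the other factor, too few for a share under 0.05, as 1 of 18 is 0.056. A real difference also adds to the residual spread of every other split, so a 0 there is no estimate of chance calls. The real split gave the most genes by sex (1 of 34, 24 genes against 4 at most in the others, and against 0 in the other balanced splits), which its 12 X- and Y-linked genes make certain. Without X- and Y-linked genes, 5 of 34 splits gave as many as the 3 genes by sex (up to 6), while the other balanced splits gave 0. By preparation the real split also gave the most genes (1 of 34, 9377 against 0) and the most receptor genes (1 of 34, 232 against 0). For the number of lists that passed with the preset correlation chance cannot be excluded, since 14 of 34 splits gave as many as the 11 by sex (up to 18) and 5 of 34 as many as the 19 by preparation (up to 22). Among the balanced splits these numbers were 6 of 18 (up to 15) and 2 of 18 (up to 19).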
